A study of Nicotiana attenuata with 6 samples.

How the data were processed

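Total RNA from roots of wild type and ir-hspro seedlings of the wild tobacco *Nicotiana attenuata* was measured on 6 single-colour arrays, 3 per genotype. The ir-hspro plants carry an inverted-repeat construct that lowers the expression of HSPRO. Per the labels' protocols, 2 seedlings of 1 genotype, 7 days old, were placed on each agar plate with a plug of the root-colonising fungus *Piriformospora indica* at 1 cm from each, and roots were taken after 14 days. The treatment label also names plates with a sterile plug; such samples were not analysed here. Cy3-labelled cRNA was made from 0.5 ug of RNA, per the labels' protocols. The labels name the tissue as roots, while the extraction text speaks of leaves; leaf and root marker lists were therefore read per array. The series design describes the arrays of each genotype as independent experiments.

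Each deposited scanner file holds the spots of 1 array of a custom Agilent design, read with Agilent Feature Extraction 9.5, per the submitters' processing notes. The processed signal is a spot intensity from which, per the file headers, background was subtracted with spatial and multiplicative detrending. The deposited intensity values were not scaled between arrays. The mean spot intensity and the median local background intensity, deposited in the same files, were used for an alternative background correction. The authors' deposited series matrix holds a linear signal per probe: set against the scanner values, it equals the processed signal divided by the array's 75th percentile over all spots, controls included, with no log scale and no centring per gene. Its medians were 0.128, 0.116 and 0.125 in the wild type arrays and 0.136, 0.129 and 0.126 in the ir-hspro arrays. The other deposited columns used were 0 or 1 flags for spots above background, saturated spots and outlier spots.

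Each array held 45220 spots, of which 43803 were not controls and covered 43533 probes; 30 probes had several spots, which were averaged. Log2 of the processed signal minus the array's own 75th percentile over non-control spots was the measure, with no pseudocount. Spots marked as non-uniform or population outliers were left out (1 to 7 per array), and 1 non-control spot per array was saturated and was kept. A probe was tested when it was well above background on all 3 arrays of at least 1 genotype, which left 29013 probes. Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, genotype only, two-sided), with Benjamini-Hochberg adjustment over all probes tested and a threshold of 0.05. A probe that no array of 1 genotype measured above background was given as a bound: the mean of the brighter group against the mean of, per array of the dimmer group, the higher of the lowest signal well above background and the probe's own signal. An adjusted p given beside a bound is that of the limma fit on the processed signal, dim values included. It does not test the bound. The bound is not strict, since a spot can lie above that lowest signal without being called well above background. Na_454_17640 lay above it on all 3 wild type arrays, and 2 of these were called well above background. An "at least" fold below is set against that level, and a bound near 1 does not exclude no change. With 3 arrays against 3, the smallest two-sided p of an exact permutation test is 0.1, so no such test can pass the threshold. The number of arrays limits the precision.

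Probes stand for assembled transcripts (contigs). In the files 33639 probes carry the entry name of the most similar database protein, such as SF3_HELAN, where the first part names the protein and the second the species; the others carry only the contig identifier. Of these names, 14172 come from land plants, and 12367 of those were taken as informative, leaving out names made of locus numbers, F-box and pentatricopeptide repeat series numbers and transposon proteins. Such a name is a resemblance, several contigs can share it, and it is not the tobacco gene's own symbol. The reference gene table (assembly NIATTr2) has no identifier in common with the contigs and was not used. HSPRO was not analysed here, because no probe in the files used carries its name, so the silencing itself could not be checked. No probe was named for the fungus.

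Gene lists were fixed before the data were examined as patterns on gene descriptions. The files hold entry names in place of descriptions, so the 26 lists were translated into entry names of land plant proteins before any difference between genotypes was computed. Of these, 25 lists had at least 5 tested genes and were tested with camera (inter-gene correlation preset at 0.01) with 1 probe per gene, that of the highest mean signal, and Benjamini-Hochberg adjustment over the lists. A gene with a left-out spot counts in a list's size and mean but not in camera or fry, which left out 1 gene in all, of the cell wall list. Counts of list members past the threshold are over all tested probes of the list, since contigs of 1 name can differ. The lists also include leaf tissue markers (photosynthesis) and root markers (nicotine biosynthesis).

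The genes named were set by a rule fixed before the data were examined. Among probes past the threshold with an informative name and groups that do not overlap, up to 12 per direction with the largest change were taken, 1 probe per name; where fewer than 4 passed in a direction, the 6 with the smallest p were taken and given as values where they were not past the threshold. For each list, up to 3 members past the threshold, or else the 1 member of smallest p, were named. These members were chosen over all tested probes of the list. Such a probe can thus be another contig than the one used in the list's mean and test.

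The slide and the scan day of each array were taken from the files. Wild type replicates 1 and 2 lay alone on slides 1 and 2, and wild type replicate 3 shared slide 3 with the 3 ir-hspro arrays. Wild type replicate 2 was scanned on a day of its own. Slide and scan day were therefore fitted as blocks. With slide as a block, the difference rests on wild type replicate 3 against the 3 ir-hspro arrays, as it does within slide 3 alone. With scan day as a block, wild type replicate 2 has no weight in the difference, which is then that of the fit without this array. These repeats are counted separately among the alternatives, which are thus not independent checks. The alternatives tried were quantile normalization, median centring, normexp background correction (offset 50) with either scaling, no filter or a stricter filter on dim probes, outlier spots kept, the series matrix values, the replicate number, slide or scan day as a block, eBayes with trend and robust options, each array left out, a 2-fold threshold, and for the lists an estimated correlation, fry and the mean of all probes of a gene. A list test with every probe counted separately was added after the data were seen. The normexp offset of 50 is added to every spot before the log2 scale is taken, which makes differences between dim spots smaller.

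The procedure was tested on simulated data for the same comparison, after a first fit of the real arrays: 6 arrays with the means and residual spreads of the 29013 tested probes and 200 changed probes. It recovered 20% of the 50 probes changed by 1.41-fold, 78% of those changed by 2-fold, 90% of those changed by 4-fold and 96% of those changed by 16-fold, with 6 false calls. A simulated shift of -0.3 on the log2 scale in 1 list was called in its direction with no call among the other lists. That shift was larger than the mean difference of any list tested in the real arrays. The simulated probes varied independently and without slide effects. The simulation therefore does not show how often probes or lists are called wrongly in the real arrays.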

Results

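Root transcripts of *Nicotiana attenuata* seedlings were compared between wild type plants and plants silenced for HSPRO (ir-hspro), all grown for 14 days with *Piriformospora indica*, a fungus that lives in roots and can promote plant growth. The comparison asks which root transcripts differ when HSPRO expression is lowered in the presence of the fungus. There were 3 arrays per genotype. The 75th percentile of the processed signal was 637, 1108 and 873 in wild type replicates 1 to 3 and 1117, 1157 and 1133 in ir-hspro replicates 1 to 3. Between 62.8% and 72.5% of the 43533 probes were well above background on an array. Correlations of log2 signals across probes, which are not independent replicates, ran from 0.986 to 0.995 between arrays, and no 2 arrays shared a value at any spot. The HSPRO transcript itself was not analysed here, since no probe carries its name. Values below are log2 signals relative to the array's 75th percentile, as mean ± SD with n = 3, and names are those of the most similar database proteins.

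In ir-hspro roots 39 probes were higher and 5 were lower than in wild type at an adjusted p under 0.05 (limma), out of 29013 tested. The largest rise among probes with an informative plant name was in SF3_HELAN, which resembles a LIM-domain protein of sunflower pollen, at -3.58 ± 0.13 in wild type and -0.08 ± 0.13 in ir-hspro, an 11.3-fold difference (log2 difference 3.50, SE 0.11, adjusted p = 3.61e-04; 2.65 with normexp background correction). The largest fall was in GDL74_ARATH, which resembles a GDSL esterase/lipase, at -1.35 ± 0.14 in wild type. It was not well above background on any ir-hspro array and was at least 20.4-fold lower there on the processed signal (limma adjusted p = 0.00189); with normexp the log2 difference was -2.82. NPP_HORVU, named for a nucleotide pyrophosphatase/phosphodiesterase of barley, was 3.84-fold higher in ir-hspro, at -0.29 ± 0.18 against 1.65 ± 0.09 (SE 0.11 on the log2 scale, adjusted p = 0.00296). AXX15_SOYBN, named for an auxin-induced protein of soybean, fell by 0.90 on the log2 scale (SE 0.09, adjusted p = 0.0289).

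The other 4 named genes that rose were fainter. STO_ARATH, named for the B-box protein salt tolerance of Arabidopsis, was at -4.75 ± 0.11 in ir-hspro and not well above background on any wild type array. Its bound was 1.46-fold higher on the processed signal (limma adjusted p = 0.0139), and its log2 difference with normexp was 0.06. AB15C_ARATH, an ABC transporter of the C family, was likewise measured only in ir-hspro, at -4.93 ± 0.15. Its bound was 1.28-fold above wild type on the processed signal (limma adjusted p = 0.0415), and its log2 difference with normexp was 0.07. The bounds of both are not strict, so no change is not excluded. CKB21_ARATH, a B-type cyclin-dependent kinase, was 2.06-fold higher in ir-hspro (log2 difference 1.04, SE 0.09, adjusted p = 0.0202; 0.24 with normexp, where the call was lost), with 1 of the 3 wild type arrays well above background. WRK16_ARATH, only named for a WRKY transcription factor of Arabidopsis, was 1.92-fold higher (log2 difference 0.94, SE 0.08, adjusted p = 0.0202). With normexp its log2 difference was 0.22 and the call was lost.

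Fewer than 4 named genes fell past the threshold, and the next by p are given as values only. The log2 difference was -0.98 (adjusted p = 0.0756) for NLTL2_ARATH, a lipid-transfer-like protein, and -0.60 (adjusted p = 0.093) for ATL4G_ARATH, a RING-H2 finger protein. It was -0.90 (adjusted p = 0.093) for PRH_ARATH, a pathogenesis-related homeodomain protein, and -0.73 (adjusted p = 0.0989) for LONH2_MAIZE, a Lon protease homolog. None of these 4 passed the threshold; NLTL2_ARATH did in 2 of 20 alternatives, PRH_ARATH and LONH2_MAIZE in 1 of 20 each and ATL4G_ARATH in 0 of 20. The other 3 probes that fell were named after their values were seen: Na_454_29023 fell by 3.34 on the log2 scale (adjusted p = 0.00822), Y1357_ARATH fell by 1.22 (adjusted p = 0.0126) and Na_454_26074 fell by 0.72 (adjusted p = 0.0492).

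**Figure D1:**
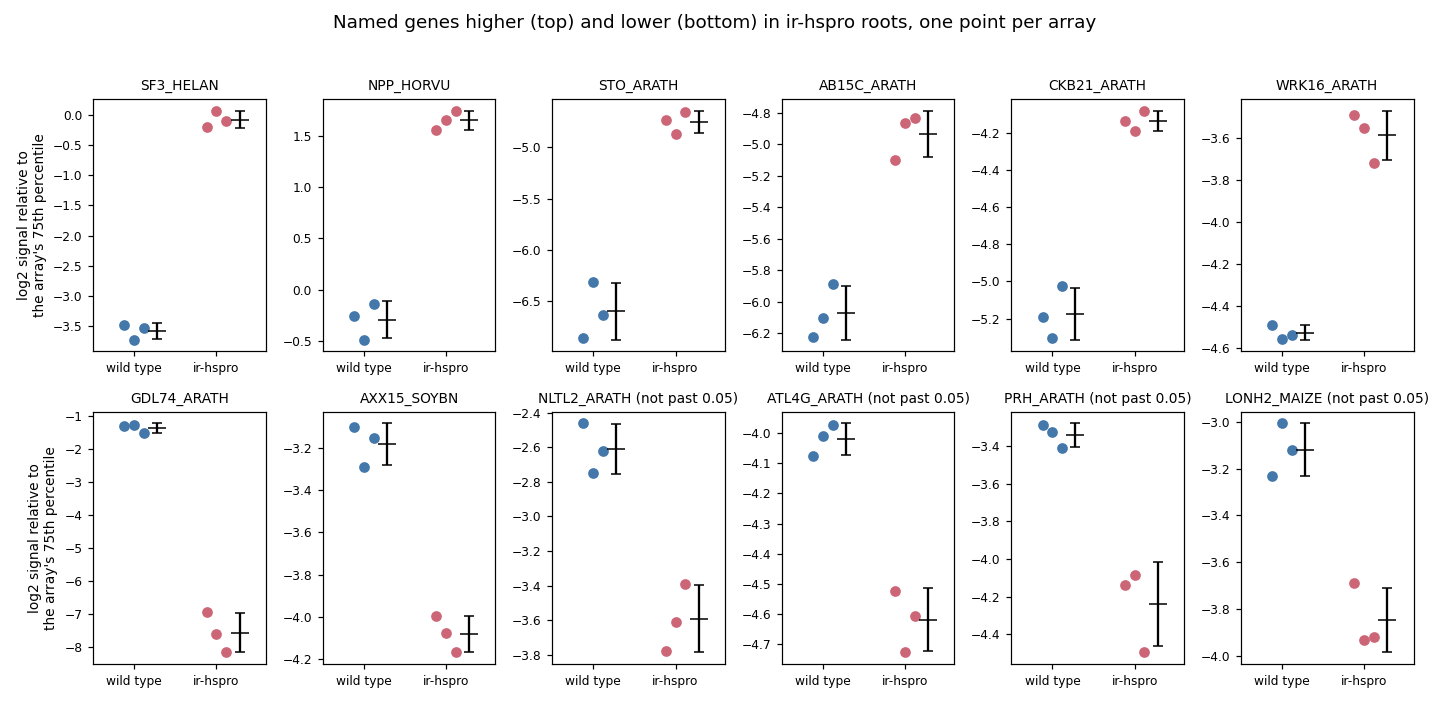
Log2 signal relative to the array's 75th percentile (vertical axis, a separate range in each panel) of the 6 named genes higher and the 6 named genes lower in ir-hspro roots; each point is 1 array and the black bars are mean ± SD of 3 arrays. SF3_HELAN lies at a mean of -3.58 in wild type and -0.08 in ir-hspro, GDL74_ARATH at -1.35 and -7.56 (not above background in ir-hspro), and the 4 panels marked as not past 0.05 have adjusted p values from 0.0756 to 0.0989.

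Among the 39 probes that rose, 28 rose by at least 2-fold, with the bound taken for the 12 that were not well above background on any wild type array. Other contigs with the same name did not always move: 6 other probes named GDL74_ARATH had log2 differences from -0.23 to 0.05, and the other SF3_HELAN probe had 0.10. Among the 24 other probes named AXX15_SOYBN, 16 had negative differences, none past the threshold. Positive differences were found in 6 of 10 other NPP_HORVU probes (range -0.09 to 0.40) and 1 of 5 other AB15C_ARATH probes (-0.10 to 0.54). They were also found in 4 of 5 other WRK16_ARATH probes (-0.35 to 1.00), and none of these probes passed the threshold. Of the 44 changed probes 8 had an informative plant name and 27 carried only a contig identifier. Contigs Na_454_27647 and Na_454_22298 were among these: the first was at least 11.4-fold higher in ir-hspro on the processed signal (adjusted p = 0.00314; 0.0623 with slide as a block), with a log2 difference of 2.07 with normexp, and the second 13.3-fold higher (adjusted p = 3.61e-04; 0.0265 with slide as a block). The groups did not overlap in any of the 44 changed probes, nor in 22.0% of all tested probes. Chance gives 10% only for arrays that are otherwise alike and a filter blind to genotype. Here the filter took probes above background on all arrays of 1 genotype, and slides were unbalanced. The excess is therefore not a measure of genotype alone. At an unadjusted p under 0.05 there were 2419 higher and 1373 lower probes, against 1451 in all given by chance.

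The scan day and slide were not balanced between the genotypes. With slide as a block, which leaves wild type replicate 3 against the 3 ir-hspro arrays, 19 probes were higher and 9 lower, of which 12 and 0 were among those above; within that slide alone, with dim probes filtered there, the counts were 53 and 83. The log2 difference with slide as a block was 3.45 for SF3_HELAN (adjusted p = 0.0265) and 1.78 for NPP_HORVU (adjusted p = 0.0454). For genes at background in 1 genotype the bound within that slide was 1.15-fold higher for STO_ARATH, 1.02-fold higher for AB15C_ARATH and 18.2-fold lower for GDL74_ARATH. Since the bound is not strict, no change is not excluded for STO_ARATH and AB15C_ARATH. The log2 difference was 0.89 for CKB21_ARATH, 0.95 for WRK16_ARATH and -0.93 for AXX15_SOYBN, with adjusted p values from 0.104 to 0.155, and -3.05 for Na_454_29023, -1.16 for Y1357_ARATH and -0.73 for Na_454_26074, with adjusted p values from 0.0811 to 0.204. With scan day as a block the counts were 37 higher and 4 lower. They were the same without wild type replicate 2, the only array of its scan day, so these 2 alternatives are 1 check. Without ir-hspro replicate 1, 2 or 3 the counts of higher probes were 14, 12 and 22. The number of alternatives in which the call was lost was 0 of 20 for SF3_HELAN, 1 of 20 for NPP_HORVU (adjusted p = 0.0505 without ir-hspro replicate 2), 1 of 19 for GDL74_ARATH (slide as a block) and 9 of 19 for STO_ARATH. It was 16 of 19 for AB15C_ARATH, 12 of 19 for CKB21_ARATH, 14 of 20 for WRK16_ARATH and 11 of 20 for AXX15_SOYBN.

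Genes of 3 lists lay lower in ir-hspro than the other named genes (camera with a preset correlation, adjusted p under 0.05 over 25 lists), and no list lay higher; with an estimated correlation none of the 3 passed (adjusted p from 0.65 to 0.737). In the cell wall loosening and structure list, which holds expansins, extensins, pectinesterases and arabinogalactan proteins, the mean log2 difference was -0.11 over 121 genes (adjusted p = 8.12e-04, and adjusted p = 0.65 with an estimated correlation). None of its 289 probes passed the threshold singly, over all probes or adjusted over the list alone; at an unadjusted p under 0.05, 67 were lower and 15 higher. The member of smallest p was EXTN3_ARATH, an extensin, with a log2 difference of -0.72 (SE 0.11, adjusted p = 0.137). The photosynthesis list, the leaf tissue markers, had a mean log2 difference of -0.16 over 46 genes (adjusted p = 0.00648, and adjusted p = 0.65 with an estimated correlation). Of its 67 probes none passed the threshold over all probes, and 3 were lower and 1 higher when adjusted over the list alone. PSBH_TOBAC, a photosystem II subunit, had the smallest p with a log2 difference of -0.55 (SE 0.09, adjusted p = 0.149), and passed in 1 of 20 alternatives. The cytosolic ribosomal protein list had a mean log2 difference of -0.03 over 91 genes (adjusted p = 0.0139, and adjusted p = 0.737 with an estimated correlation). None of its 200 probes passed the threshold singly or adjusted over the list alone, and its member of smallest p, RL281_ARATH, went the other way with a log2 difference of 1.28 (adjusted p = 0.299). That probe was well above background on 1 of the 3 wild type arrays, and its difference ran from 0.05 to 2.03 over the alternatives.

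The call was lost in 2 of 24 alternatives for the cell wall list, 5 of 24 for photosynthesis and 8 of 24 for the ribosomal proteins. For each of the 3 lists it was lost with an estimated correlation and with fry. All other alternatives kept the preset correlation of 0.01, so they do not test it. The estimated correlations were higher, at 0.06, 0.10 and 0.14. The fry test, which asks whether the genes of a list move one way on balance and does not compare them with other genes, gave adjusted p values of 0.197, 0.261 and 0.283. At an unadjusted p under 0.05 there were 6 lists with the preset correlation, 0 with an estimated correlation and 6 with fry. With slide as a block the mean log2 differences were -0.07 for the cell wall list (adjusted p = 0.00686), -0.19 for photosynthesis (adjusted p = 5.42e-05) and -0.06 for the ribosomal proteins (adjusted p = 1.02e-05). With scan day as a block they were -0.08 (adjusted p = 0.00554), -0.09 (adjusted p = 0.102) and -0.03 (adjusted p = 0.00788). Without wild type replicate 3 the adjusted p was 0.067 for photosynthesis and 0.309 for the ribosomal proteins (mean -0.02), without wild type replicate 2 it was 0.14 for photosynthesis (mean -0.09), and without ir-hspro replicate 3 it was 0.186 for the ribosomal proteins (mean -0.01). Without wild type replicate 1 the photosynthesis mean was -0.24, and without ir-hspro replicate 1 the ribosomal mean was -0.05. The ribosomal mean was -0.0022 with quantile normalization (adjusted p = 0.697), -0.06 with normexp (adjusted p = 0.297) and -0.02 with both (adjusted p = 0.492).

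The leaf and root markers differed within genotypes as well. The median log2 signal of the photosynthesis probes was -2.75, -1.84 and -1.77 in wild type replicates 1 to 3 and -2.13, -2.21 and -2.13 in ir-hspro replicates 1 to 3. The median of the 4 rubisco small subunit probes was -3.07, 0.03 and -0.16 in wild type replicates 1 to 3 and -1.79, -1.23 and -7.2e-05 in ir-hspro replicates 1 to 3. The median of the nicotine biosynthesis probes, the root markers, was 0.14, 0.81 and 0.41 in wild type and -0.01, 0.42 and 0.30 in ir-hspro. That list had 3 tested genes, too few for the list test, and none of its 6 probes passed the threshold; IFRH_TOBAC, an isoflavone reductase-like protein, had a log2 difference of -0.16 (adjusted p = 0.625).

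**Figure D2:**
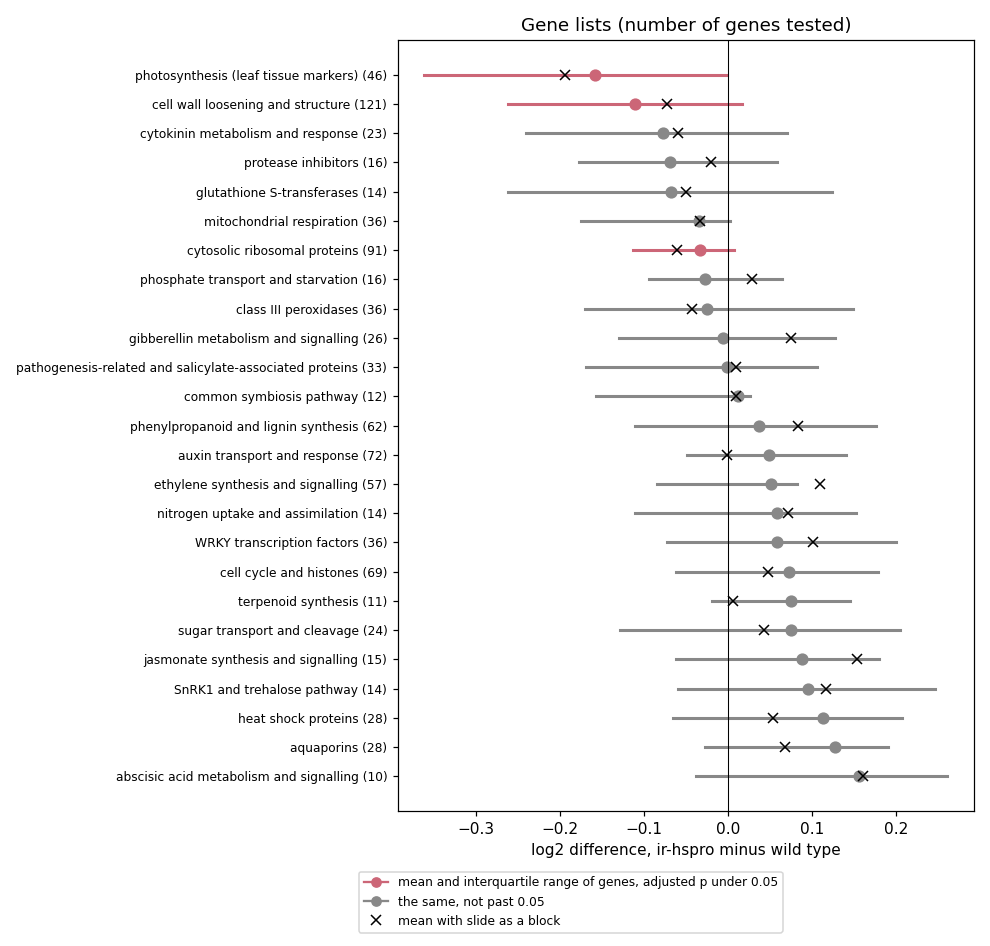
Mean log2 difference, ir-hspro minus wild type (horizontal axis), of the genes of each of 25 lists, with the number of genes in brackets; bars are the interquartile range over genes, red marks an adjusted p under 0.05 by camera with the preset correlation, and crosses give the mean with slide as a block. The 3 red lists have means of -0.16 (photosynthesis), -0.11 (cell wall) and -0.03 (cytosolic ribosomal proteins); none of the 3 passes with an estimated correlation.

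Hormone and defence lists did not pass the list test. The mean log2 difference was 0.09 over 15 genes for jasmonate synthesis and signalling (adjusted p = 0.419; past the threshold in 2 of 24 alternatives, with 0.0351 and a mean of 0.15 with slide as a block), and TIF7_ARATH had 0.44 (adjusted p = 0.3). The pathogenesis-related and salicylate-associated list had a mean of -0.0013 over 33 genes (adjusted p = 0.703), and 2 of its 80 probes were higher when adjusted over the list alone. A PR5_ARATH probe, named for a thaumatin-like protein, had a log2 difference of 0.45 (adjusted p = 0.149). The 4 other probes of that name went the other way, from -0.34 to -0.09. Ethylene synthesis and signalling had a mean of 0.05 and a median of -0.01 over 57 genes (adjusted p = 0.757), with 0.55 for ACCH1_ARATH. Gibberellin metabolism and signalling had a mean of -0.0052 and a median of 0.04 over 26 genes (adjusted p = 0.976), with 1.31 for G2OX1_ARATH, a gibberellin 2-oxidase. Abscisic acid metabolism and signalling had the highest mean, 0.16 over 10 genes (adjusted p = 0.161), with 0.72 for NCED2_ARATH, an epoxycarotenoid dioxygenase. In the auxin list 1 of 169 probes fell past the threshold, the AXX15_SOYBN probe above, and 2 were lower when adjusted over the list alone; its mean over 72 genes was 0.05 (adjusted p = 0.419). The cytokinin list had a mean of -0.08 over 23 genes (adjusted p = 0.419), 1 probe higher and 1 lower when adjusted over the list alone, and 1.57 for ZOX_PHAVU, a zeatin O-xylosyltransferase (adjusted p = 0.15). In the WRKY list 1 of 80 probes rose, the WRK16_ARATH probe above, over all probes and adjusted over the list alone; the mean over 36 genes was 0.06 (adjusted p = 0.419). The protease inhibitors had a mean of -0.07 over 16 genes (adjusted p = 0.424), with 0.61 for IP2X_SOLTU. The common symbiosis list had a mean of 0.01 and a median of -0.01 over 12 genes (adjusted p = 0.703), with 0.82 for NO551_SOYBN. Its pattern also took in any protein described as a nodulin or by nodulation or mycorrhiza, so it is wider than that pathway. None of these single genes other than AXX15_SOYBN and WRK16_ARATH passed the threshold. ZOX_PHAVU passed in 5 of 20 alternatives, PR5_ARATH in 2 of 20 and G2OX1_ARATH in 1 of 20. The list means used other contigs for some of these names: 0.39 for TIF7_ARATH, 0.03 for ACCH1_ARATH, -0.18 for G2OX1_ARATH, 0.20 for AXX15_SOYBN and 0.01 for ZOX_PHAVU. The list test pointed up for ethylene, with its mean, and for gibberellin, with its median, and down for symbiosis, with its median.

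The lists of metabolism, transport and growth did not pass either, and no single member passed over all probes. Phenylpropanoid and lignin synthesis had a mean log2 difference of 0.04 over 62 genes (adjusted p = 0.36); at an unadjusted p under 0.05, 18 of its 121 probes were higher and 4 lower, and DFRA_MALDO, a dihydroflavonol reductase, had 0.68 (adjusted p = 0.141). Terpenoid synthesis had a mean of 0.07 over 11 genes (adjusted p = 0.439), with 0.32 for HMDH3_SOLTU; the list passed in 1 of 24 alternatives, normexp (adjusted p = 0.0358). The class III peroxidases had a mean of -0.02 over 36 genes (adjusted p = 0.612), with -0.51 for PER16_ARATH. The list means used other contigs for some of these names: 0.07 for DFRA_MALDO, -0.08 for HMDH3_SOLTU and -0.29 for PER16_ARATH. The glutathione S-transferases had a mean of -0.07 over 14 genes (adjusted p = 0.399), with -0.47 for GSTF3_ARATH and 2 probes lower when adjusted over the list alone. Sugar transport and cleavage had a mean of 0.08 over 24 genes (adjusted p = 0.419). SUS1_MAIZE, a sucrose synthase, was not well above background on any wild type array and had a bound, which is not strict, of 1.09-fold higher in ir-hspro. Its limma fit gave a log2 difference of 0.84 (adjusted p = 0.197), which turned to -0.10 in 1 of 19 alternatives. The SnRK1 and trehalose list had a mean of 0.10 over 14 genes (adjusted p = 0.498), with 0.64 for ASNS_MAIZE. Phosphate transport and starvation had a mean of -0.03 over 16 genes (adjusted p = 0.934), with 1 probe higher when adjusted over the list alone. PPA1_SOLLC had a bound of 1.02-fold, which is not strict. Its limma fit gave a log2 difference of 0.59 (adjusted p = 0.0569), which turned to -0.15 in 1 of 19 alternatives. Nitrogen uptake and assimilation had a mean of 0.06 and a median of -0.05 over 14 genes (adjusted p = 0.934), with 0.86 for NIA_PETHY, a nitrate reductase; the list test pointed down, with the median.

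Mitochondrial respiration had a mean log2 difference of -0.03 over 36 genes (adjusted p = 0.11; past the threshold in 2 of 24 alternatives, both using all probes of a gene, the lowest 0.00418), with -0.30 for NU5M_ARATH. The heat shock proteins had a mean of 0.11 over 28 genes (adjusted p = 0.268), and 1 of 46 probes was higher when adjusted over the list alone. HSP7S_SPIOL had a bound of 1.02-fold, which is not strict. Its limma fit gave a log2 difference of 1.38 (adjusted p = 0.0569), which passed in 5 of 19 alternatives and turned to -0.09 in 1. Cell cycle genes and histones had a mean of 0.07 over 69 genes (adjusted p = 0.419), with 0.55 for H1_MAIZE, a histone H1. The aquaporins had a mean of 0.13 over 28 genes (adjusted p = 0.133; past the threshold in 2 of 24 alternatives, both with normexp, the lowest 0.00691), with 0.79 for PIP22_ARATH (adjusted p = 0.291). For every list of these paragraphs where no count is given, no probe passed adjusted over the list alone.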

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

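Of the settings, the list test with every probe counted separately was chosen only after the data were seen. The counts of changed probes moved with many settings, while no named gene or list past its threshold changed direction under any alternative run. The 8 named genes past the threshold gave 156 values under the alternatives, of which 92 kept the call and 64 lost it in the same direction. The 3 lists gave 72, of which 57 kept it, all with the preset correlation, and 15 lost it. Of the 39 higher and 5 lower probes, the counts became 25 and 9 with normexp background correction, 16 and 2 with no filter on dim probes, 19 and 9 with slide as a fixed block, and 63 and 23 with trend and robust options. Lower probes numbered 8 with quantile normalization, 21 (with 55 higher) with normexp and quantile normalization, 83 (with 53 higher) within the slide that held both groups, and 3 at 2-fold or more. With probes above background on all 6 arrays, 22 were higher. Leaving out 1 array gave 12 to 37 higher and 1 to 4 lower probes and 1 to 3 lists, with 14, 12 and 22 higher without ir-hspro replicates 1, 2 and 3 and 1 list without wild type replicate 3. The 3 lists fell to 0 with an estimated correlation and 0 with fry. The stricter filter on dim probes and the 2-fold threshold leave fewer probes by construction. A fit with fewer arrays holds fewer values per probe, while its filter on dim probes asks for fewer arrays. For those fits and the other settings the cause was not tested.

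Whether the replicate numbers pair the arrays stays open. The correlation of deviations from the group means was 0.16, 0.10 and -0.0022 for the same-numbered arrays. Among the ir-hspro arrays, wild type replicates 1 and 2 correlated best with their own number. Wild type replicate 3 did not, with 0.03 for ir-hspro replicate 2. With the replicate block 18 probes were higher and 3 lower, and the cytosolic ribosomal list had an adjusted p of 0.0538. With normexp the log2 difference of STO_ARATH was 0.06, of AB15C_ARATH 0.07, of CKB21_ARATH 0.24 and of WRK16_ARATH 0.22. The last 2 were 1.04 and 0.94 with the processed signal. With normexp and quantile normalization they were 0.27, 0.29, 0.42 and 0.35 in that order, none past the threshold. The normexp offset shrinks differences between dim spots. Under 75th percentile scaling it also lifts dim spots most on wild type replicates 1 and 3, the arrays of lowest 75th percentile. Its share in these values was not tested, so they do not decide whether the rises are real. Median centring, the series matrix values, outlier spots kept and slide as a random block kept each count within 1.5 times.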

Other observations

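The tests of families, of plastid-coded probes and of contigs without a name, the division at 8-fold of probes seen in only 1 genotype with both of its tests, the rubisco and slide tests of the photosynthesis list, the tests of the share of higher probes and the count of probes over other splits were chosen only after the result was seen. Families were also formed from the opening letters of the entry names, 33 families with at least 10 genes measured on all 6 arrays, which leaves out 1 AGP gene with an outlier spot. Arabinogalactan proteins (AGP) had a mean log2 difference of -0.22 over 16 genes, 13 of them below 0 (camera adjusted p = 4.25e-04, estimated-correlation adjusted p = 0.878). The plasma membrane aquaporins (PIP) had a mean of 0.25 over 11 genes, 1 of them below 0 (adjusted p = 0.0462, estimated-correlation adjusted p = 0.878), and the Aux/IAA proteins (IAA) had 0.23 over 18 genes, 5 below 0 (adjusted p = 0.0459, estimated-correlation adjusted p = 0.878). The AGP genes are part of the cell wall list, PIP of the aquaporins and IAA of the auxin list, so these are not independent of the lists. Under the other 4 scalings and background corrections the means kept their signs, from -0.23 to -0.19 for AGP, from 0.23 to 0.28 for PIP and from 0.10 to 0.21 for IAA.

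Plastid-coded and nucleus-coded photosynthesis probes were read apart. The 10 plastid-coded probes had a median log2 difference of -0.38, with 9 of 10 below 0, and their mean per array was -1.03 ± 0.08 (SD, n = 3) in wild type and -1.37 ± 0.17 in ir-hspro, without overlap (exact permutation p = 0.1, two-sided, the smallest possible). The 57 nucleus-coded probes had a median of -0.12, at -2.04 ± 0.35 in wild type and -2.15 ± 0.13 in ir-hspro (exact permutation p = 0.7, two-sided). The difference between both kinds was not tested. Changed probes carried only a contig identifier more often than tested probes did, 27 of 44 (61.4%) against 5343 of 29013 (18.4%; Fisher's exact test, two-sided, p = 3.47e-10). That test treats probes as independent, so its p is too small if several contigs stand for 1 transcript.

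Probes seen in only 1 genotype were 13 of the 44 changed probes, 12 above background in ir-hspro alone and 1 in wild type alone. For those with a fitted difference of at least 8-fold, whose bounds start at 2.65-fold, a difference between slides is argued against. The same rule of detection and fitted size, without a threshold on p, gave 0 probes between slide 3 and the other slides. Between the genotypes it gave 8, and probes under 8-fold were not covered. Values filled in for dim spots may be a source. The test set beforehand was the median size of the difference with normexp over all 13. It gave 0.89 on the log2 scale (quartiles 0.27 and 1.76), under the limit of 1 set for this explanation. The normexp offset also shrinks differences between dim spots, and these probes were dim in 1 genotype. A real difference could therefore fall under that limit too, and the test does not decide. A division at a fitted 8-fold, made after that test, decides nothing either. The size of the change all but fixes the values of the division. These were a smallest bound of 2.65-fold over the 7 larger changes and a median with normexp of 0.17 over the 6 smaller ones. Filled-in values and a difference between the 2 seed lines, whether through HSPRO or not, both stay open, the last untested since the design holds 1 silenced line.

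The lower photosynthesis list may come from unequal amounts of leaf tissue, and this cannot be told apart: the rubisco small subunit probes differed by 0.24 on the log2 scale with a 95% interval from -1.99 to 2.46, from the pooled SD of 3 arrays per genotype. The scaling of the arrays is argued against, since the list's mean stayed at -0.14 or lower under the other 4 scalings and background corrections. A slide difference stays open too: with slide as a block the mean was -0.19, but this rests on 1 wild type array. The genotype itself remains among the open explanations.

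More probes were higher than lower in ir-hspro, 88.6% of the 44. Scaling is argued against as the whole cause: the lowest share under the other 4 scalings and background corrections was 72.4% (lowest bound of their exact 95% intervals, which treat probes as independent, 55.6%), and with each array left out under them it was at least 63.2%. The dimmest array, wild type replicate 1, is argued against as well, since the share without it was 90.3%. A slide difference stays open, since the share was 67.9% with slide as a block (exact 95% interval 47.6% to 84.1%) and 39.0% within the slide that held both groups, with a single wild type array. No biological explanation for the direction was tested.

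With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 39 higher probes and 5 lower ones, and the highest count of any other split was 0, so 1 of the 10 splits reached either count. For the lists the real split gave 3 and the highest other split gave 4, and 4 of the 10 splits gave at least 3; the split with 4 lists set wild type replicate 1 with ir-hspro replicates 1 and 3 and follows neither slide nor scan day.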
